A study of Homo sapiens with 13 samples.

How the data were processed

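RNA was measured by sequencing of polyadenylated transcripts with a stranded mRNA library kit in human microglia-like cells. The cells were differentiated from PGP1, an established induced pluripotent stem cell line. The labels give each of 13 libraries a genotype and a batch, A or B. WT had 4 libraries, with replicates 1 and 2 in batch A and replicates 3 and 4 in batch B. GRN KO had 3 libraries, with replicate 1 in batch A and replicates 2 and 3 in batch B. TMEM106B KO had 2 libraries, replicates 1 and 2, both in batch B. Double KO, lacking both genes, had 4 libraries, with replicates 1 and 2 in batch A and replicates 3 and 4 in batch B. Replicate numbers only name libraries and pair none. Nothing in the labels says that replicates were separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

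The deposited table of each library held raw whole-number counts per gene beside RPKM values, per the file headers. Reads were aligned with GSNAP to GRCh38, per the submitters' processing notes; the counting tool, its strand setting and the annotation release are not given in the sources used here. The RPKM values were scaled by the authors, per the file headers, and their denominators were larger than the sum of the deposited counts, which came to 78.3 to 84.0% of them. RPKM values were checked and not used for any test. Each table listed 58302 Ensembl identifiers, of which 58039 (99.5%) were given symbols from GENCODE release 29, the source of all coordinates here, and 57532 were also found in the gene name table used here. 0 rows named no gene. Total counts ranged from 21521850 to 27750488 per library. A count of 0 was compared with a floor of 3 counts per library, and such floors cover counting error only. No 2 libraries agreed within sampling noise, since the smallest chi-square per degree of freedom between any pair was 2.34. Pairs of the same genotype were closer in batch B, at 2.34 for Double KO, 5.63 for GRN KO, 10.83 for TMEM106B KO and 11.76 for WT. In batch A they were at 18.05 for Double KO and 29.89 for WT. Tests in batch B alone rest on that smaller spread, which may be technical.

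The following choices were made before the data were examined: the tests, the libraries in each fit, the gene lists, the rule for naming genes and most alternatives. Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, robust spread estimate, filterByExpr with a count minimum of 10) in R 4.3.3. The fit held all 13 libraries, 1 mean per genotype and a batch term, with 8 residual degrees of freedom. It covered 16776 genes and gave a common biological coefficient of variation of 12.5%. All adjusted p-values of genes are from this test with Benjamini-Hochberg adjustment within a comparison, at a threshold of 0.05. Log2 fold changes are from the fit. The standard errors (SE) given with them are their absolute size divided by the square root of the F statistic, which is not reliable for groups near 0 counts. Levels are CPM, counts scaled to a common library total after TMM, given as mean ± SD over libraries. PCA and list scores used log2 CPM with a prior count of 2. The comparisons were each knockout against WT, Double KO against each single knockout, and the interaction, which is the log2 difference of Double KO from the sum of the single effects.

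24 gene lists with tested members were compared with all other genes by camera (limma 3.58.1), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. They covered homeostatic microglia, disease-associated microglia, lysosomal proteins, V-ATPase subunits, autophagy, cholesterol synthesis, cholesterol efflux and LXR targets, the interferon response, inflammatory cytokines and NF-kB targets, MHC class II, complement, cell cycle, ER stress, glycolysis and hypoxia, mitochondrially encoded mRNAs, and extracellular matrix and adhesion. 8 further lists held markers of monocytes, pluripotent stem cells, neural, fibroblast or mesenchymal, endothelial, erythroid or megakaryocyte, mast or granulocyte, and epithelial or hepatic cells. The same lists were tested with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. With an estimated correlation, the calls that held were inflammatory cytokines and NF-kB targets in GRN KO against WT, in Double KO against GRN KO and in the interaction, and epithelial or hepatic markers in TMEM106B KO against WT. A list score is the mean log2 difference of a list's members from the WT libraries of the same batch, for 1 library.

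Named genes followed a fixed rule. GRN and TMEM106B came first. For each knockout against WT and for Double KO against GRN KO, the rule took up to 6 genes with the largest rise and 6 with the largest fall. These had to pass the threshold, have a mean log2 CPM of at least 1 and show no overlap between groups within a batch. Up to 2 members per list with the lowest adjusted p were added. Y-linked genes, XIST and genes without a symbol were left out. Some genes named by the rule are not reported here. CTSF, with 0 counts in every library lacking TMEM106B, was named by the rule as a list member.

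On simulated counts for 16462 genes, the edgeR step was tested with genes changed 1.5-, 2- or 4-fold. It recovered 76.1, 80.6 and 95.5% of them for GRN KO against WT, where 12 of 180 calls were false. For TMEM106B KO against WT it recovered 44.8, 83.6 and 93.9%, where 9 of 157 calls were false. For Double KO against WT it recovered 67.2, 89.6 and 98.5%, where 13 of 183 calls were false. In a simulated test of camera, a list of 30 genes raised 1.3-fold had an adjusted p of 2.6e-44, and 0 of 20 unchanged lists passed. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. The simulated counts held 1 batch effect for all genotypes, so a batch difference that varies between genotypes was not tested.

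Alternatives were RLE and upper-quartile factors, no low-count filter or CPM of at least 1 in at least 4 libraries, the DESeq2 1.42.0 Wald test, no batch term, each batch alone, only the groups compared, a non-robust spread, a 2-fold size threshold, and leaving out each library in turn. Comparisons against the same WT libraries share chance values, so 30 simulated sets of unchanged groups were compared with them, and WT libraries were also split between comparisons. A held-out measure chose genes in batch B from GRN KO and WT and read them in batch A, where no library had been used for the choice. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.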

Results

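Expression of all genes was compared between human microglia-like cells of 4 genotypes, made from 1 induced pluripotent stem cell line. GRN encodes progranulin, a secreted and lysosomal protein whose haploinsufficiency causes frontotemporal dementia. TMEM106B encodes a lysosomal membrane protein and is a known genetic modifier of that disease. According to the series title, the study asked whether lower TMEM106B rescues GRN haploinsufficiency; the cells measured here were knockouts. There were 4 WT, 3 GRN KO, 2 TMEM106B KO and 4 Double KO libraries, spread over batches A and B, with no TMEM106B KO library in batch A. Total counts, in replicate order, were 23217931, 23965539, 23661253 and 24977981 for WT and 22741951, 26763743 and 23576354 for GRN KO. They were 24880276 and 26355047 for TMEM106B KO, and 23218335, 24063860, 21521850 and 27750488 for Double KO.

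The batches differed more than the genotypes did. PSAP, the precursor of the saposins, was the most abundant gene in every batch A library at 1.41 to 1.93% of counts, and SPP1, which encodes osteopontin, in every batch B library at 1.62 to 2.94%. The first principal component held 45.6% of the variance and separated the batches, with scores of -68.2 to -52.4 in A and 18.0 to 54.4 in B. The second held 20.2% and set the TMEM106B KO libraries apart, at -42.1 and -78.2. In the edgeR test of the batch term, 9292 of 16776 genes (55.4%) differed, 4608 higher and 4684 lower in batch B.

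GRN mRNA (ENSG00000030582, chromosome 17, 44345086 to 44353102, plus strand) was 2099 ± 1020 CPM in WT (SD, n = 4), with 2387 and 3415 in batch A and 1228 and 1367 in batch B. It was 71.7 ± 13.8 CPM in GRN KO (n = 3), 41.4 ± 0.907 in Double KO (n = 4) and 1667 ± 11.1 in TMEM106B KO (n = 2). The fall was 26.3-fold in GRN KO (log2 fold change -4.71, SE 0.28, adjusted p = 9.23e-06) and 47.0-fold in Double KO (log2 -5.55, SE 0.25, adjusted p = 9.31e-07). GRN in TMEM106B KO had a log2 difference of 0.02 from WT in the pooled fit (SE 0.28, adjusted p = 0.99). Within batch B, which holds all TMEM106B KO libraries, its 1667 ± 11.1 CPM lay above the 1228 and 1367 CPM of WT, so an unchanged GRN level cannot be concluded. Double KO and GRN KO were not separated (log2 -0.84, SE 0.23, adjusted p = 0.101). TMEM106B mRNA (ENSG00000106460, chromosome 7, 12211241 to 12243367, plus strand) was lower in WT of batch B, 7.83 and 6.67 CPM, than of batch A, 25.4 and 34.3 CPM. It was 1.77 ± 0.265 CPM in TMEM106B KO and 1.09 ± 0.434 in Double KO, a fall of 5.12-fold (log2 -2.36, SE 0.34, adjusted p = 0.0027) and 15.1-fold (log2 -3.92, SE 0.27, adjusted p = 6.7e-06). GRN KO libraries held 26.3 CPM in batch A and 12.5 and 13.6 CPM in batch B, not past the threshold against WT (log2 0.37, SE 0.23, adjusted p = 0.408). Every library thus had its targeted genes below every library that kept them. Where the edits lie within the genes was not analysed here, so remaining counts do not say whether protein remained.

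**Figure D1:**
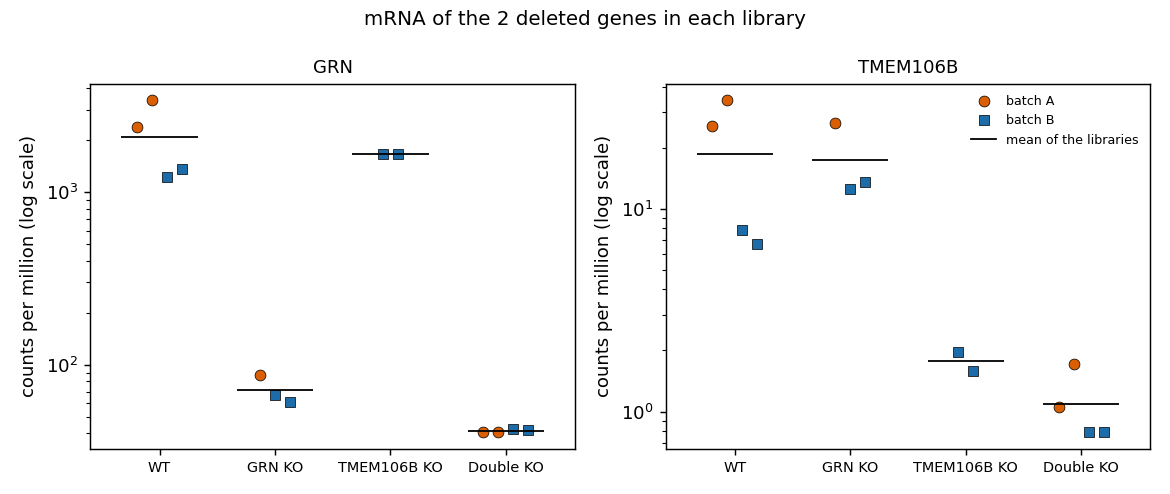
GRN and TMEM106B in CPM on a log axis, 1 point per library by genotype, with orange circles for batch A, blue squares for batch B and a line at the mean of the libraries. GRN lay between 40.6 and 87.2 CPM in GRN KO and Double KO and at 1228 CPM or more elsewhere, and TMEM106B lay below 2 CPM in TMEM106B KO and Double KO.

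The comparison of GRN KO with WT asked what the knockout of GRN changes. IRAK4, a kinase that carries signals from Toll-like and interleukin-1 receptors, was nearly absent: its counts were 0, 4 and 1 in the GRN KO libraries, or 0.0641 ± 0.0769 CPM (n = 3), against 44.8 ± 4.08 CPM in WT (n = 4). PUS7L, which starts 127 bp from IRAK4 in the opposite direction, had 0, 1 and 3 counts against 35.3 ± 7.89 CPM. Both were past the threshold (log2 -9.20, SE 0.24, adjusted p = 1.08e-10 for IRAK4 and log2 -9.24, SE 0.26, adjusted p = 1.84e-10 for PUS7L), and at so few counts the size of these falls depends on the prior count. Neither loss was seen in Double KO, with 44.5 ± 6.44 CPM of IRAK4 and 29.2 ± 1.26 of PUS7L (n = 4), nor in TMEM106B KO, with 50.8 ± 1.6 and 48.9 ± 1.43 (n = 2). IRAK4 lies on chromosome 12 (43758944 to 43789543, plus strand) and PUS7L beside it (43718993 to 43758817, minus strand). Of the other tested genes within 1 Mb, looked up after the loss was seen, 0 of 2 passed edgeR's threshold (TWF1, adjusted p = 0.723; TMEM117, adjusted p = 0.056). EHHADH, an enzyme of peroxisomal fatty acid oxidation, fell 36.4-fold (log2 -5.18, SE 0.17, adjusted p = 1.09e-09), from 8.54 to 0.22 CPM. TMEM176B, a membrane protein of myeloid cells, fell 7.74-fold (log2 -2.95, SE 0.16, adjusted p = 2.63e-07). ADCY1, an adenylate cyclase, rose 9.65-fold (log2 3.27, SE 0.41, adjusted p = 0.00251), and DPP4, a surface peptidase, rose 5.62-fold (log2 2.49, SE 0.39, adjusted p = 0.009). CSF2RA, a subunit of the GM-CSF receptor, rose 21.7-fold (log2 4.44, SE 0.23, adjusted p = 3.43e-06); it has identical copies on the X and Y chromosomes, so its counting is uncertain.

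The list of inflammatory cytokines and NF-kB targets was lower in GRN KO as a group. Of 22 members 0 rose and 10 fell (14 fell adjusted over the list alone), with a median log2 of -0.76; the camera adjusted p was 7.07e-20 and the adjusted p = 0.00171 with an estimated correlation. TNF, the central inflammatory cytokine, fell 3.46-fold (log2 -1.79, SE 0.14, adjusted p = 2.07e-05). It was 5.45 CPM in the GRN KO library of batch A against 14.9 ± 0.748 in WT, and 18.3 ± 0.479 against 72.5 ± 4.0 in batch B. TNFAIP3, which encodes the NF-kB inhibitor A20, fell 1.93-fold (log2 -0.95, SE 0.09, adjusted p = 0.000119), and CXCL8, a neutrophil chemokine, fell by 1.65 on the log2 scale (SE 0.17, adjusted p = 0.000268). Within batches the list's median was -0.61 in A, from 1 GRN KO library and with 0 of 22 members past edgeR's threshold (9 lower and 1 higher at an unadjusted p under 0.05), and -0.53 in B (14 members fell and 2 rose, camera adjusted p = 8.79e-12). Its scores were -0.66 in the GRN KO library of batch A and -0.68 and -0.70 in those of batch B.

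**Figure D2:**
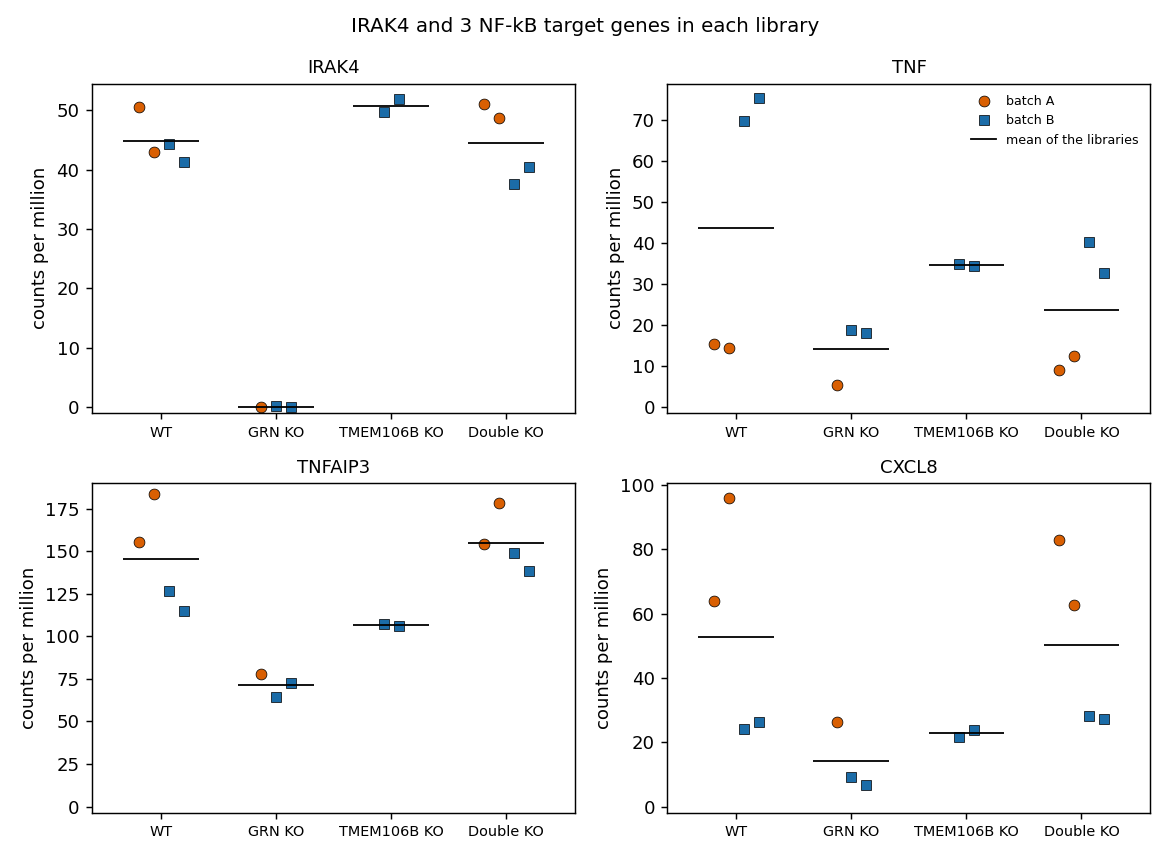
IRAK4, TNF, TNFAIP3 and CXCL8 in CPM on linear axes, 1 point per library by genotype, with orange circles for batch A, blue squares for batch B and a line at the mean of the libraries. IRAK4 was at 0.149 CPM or below in the 3 GRN KO libraries, and TNFAIP3 was lowest there at 71.7 ± 6.86 CPM.

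Lysosomal proteins were higher in GRN KO by a median log2 of 0.27, with 5 of 49 members up and 0 down (24 up and 1 down adjusted over the list alone; camera adjusted p = 3.75e-10). The call was not kept by the other test, with adjusted p = 0.61 with an estimated correlation. LAMP1, an abundant lysosomal membrane protein, rose 1.59-fold (log2 0.67, SE 0.11, adjusted p = 0.00592). Lysosomal scores differed by batch, at -0.00 in the GRN KO library of batch A and 0.53 and 0.51 in batch B, where 42 members rose and 1 fell. Disease-associated microglia genes had a pooled median of 0.51, with 0 risen and 2 fallen members (9 risen and 2 fallen adjusted over the list alone). The camera adjusted p was 9.74e-05, with adjusted p = 0.61 with an estimated correlation. In batch B alone 18 of 25 members rose and 2 fell, with a median of 0.83, and in batch A the median was 0.12 from 1 GRN KO library. In batch B alone this list was also higher against WT in Double KO, where 17 rose and 3 fell (median 0.87, camera adjusted p = 3.74e-19). In TMEM106B KO 13 rose and 2 fell there (median 0.41, camera adjusted p = 1.5e-10), while in the pooled test by DESeq2 0 rose and 1 fell. Interferon response genes went opposite ways. Their score was -0.36 in batch A and 1.64 and 1.78 in batch B. The pooled median of 0.73 (1 of 38 members up, 0 down, 0 adjusted over the list alone) had a camera adjusted p of 1.07e-08 and adjusted p = 0.61 with an estimated correlation. BST2, an interferon-induced membrane protein and the member that passed, had a log2 difference of 0.55 (SE 0.13, adjusted p = 0.0397). The call was lost without WT replicate 1 (0.0557), WT replicate 3 (0.15), WT replicate 4 (0.166), GRN KO replicate 2 (0.167) or GRN KO replicate 3 (0.17). Mesenchymal markers stood at a score of -3.61 in the GRN KO library of batch A and at 0.13 and 0.07 in those of batch B. Their pooled median was -4.27 (0 of 13 passed in edgeR, 4 lower at an unadjusted p under 0.05 and 3 by DESeq2). The camera adjusted p was 0.0357 (0.138 without WT replicate 1, 0.256 without WT replicate 2 and 0.312 without GRN KO replicate 1), with adjusted p = 0.619 with an estimated correlation.

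**Figure D3:**
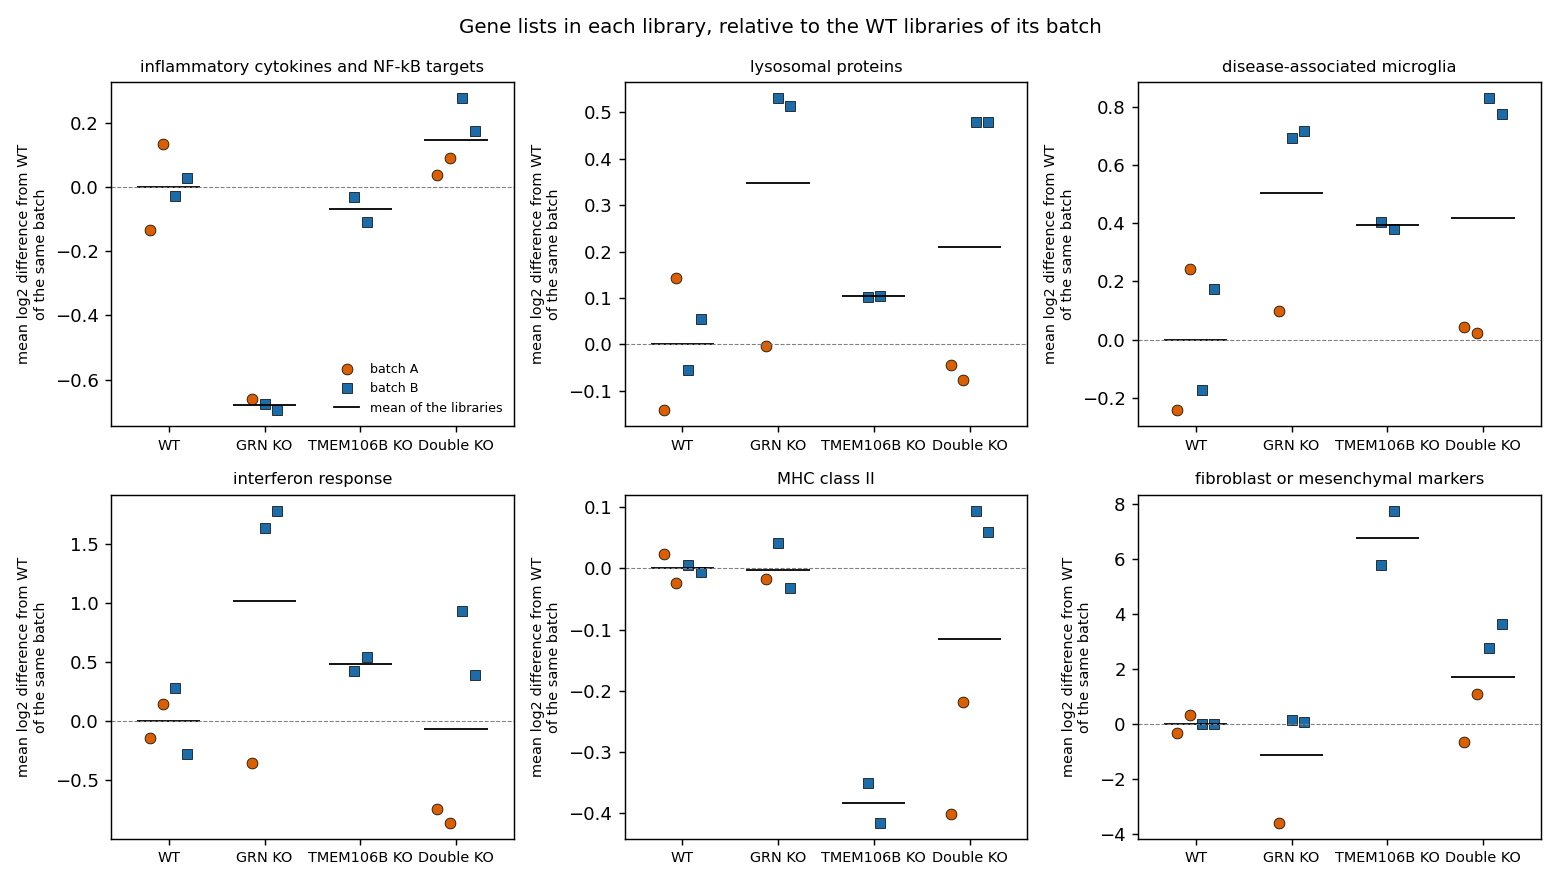
Mean log2 difference of 6 gene lists from the WT libraries of the same batch, 1 point per library by genotype, with orange circles for batch A, blue squares for batch B and a dashed line at 0. NF-kB targets lay between -0.70 and -0.66 in the GRN KO libraries, MHC class II at -0.35 and -0.42 in TMEM106B KO, and mesenchymal markers at 5.76 and 7.75 in TMEM106B KO.

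Cell cycle genes had a median log2 of -0.59 in GRN KO (0 of 28 rose, 1 fell, 0 adjusted over the list alone; camera adjusted p = 8.07e-09 and adjusted p = 0.61 with an estimated correlation). Homeostatic microglia genes (2 of 20 rose, 5 adjusted over the list alone) had a camera adjusted p of 0.0153, and V-ATPase subunits (0 of 18 in edgeR, 6 higher at an unadjusted p under 0.05 and 1 by DESeq2) of 0.00994. Autophagy genes (1 of 25 rose) had a camera adjusted p of 0.0312, and extracellular matrix and adhesion genes (3 of 23 rose, 5 adjusted over the list alone) of 0.0112. Each of these lists had adjusted p = 0.61 with an estimated correlation. Extracellular matrix genes turned direction between the batches, with a score of -0.60 in the GRN KO library of batch A and 0.77 and 0.84 in those of batch B. Without WT replicate 3 the call ended for V-ATPase subunits (0.0786), autophagy (0.0874) and extracellular matrix genes (0.0951). The autophagy call also ended without GRN KO replicate 1 (0.0535), GRN KO replicate 3 (0.0629) or WT replicate 4 (0.101), and the matrix call without GRN KO replicate 3 (0.0629) or WT replicate 4 (0.0663). Lists not past camera's threshold were cholesterol synthesis (adjusted p = 0.0678), cholesterol efflux and LXR targets (0.929, median -0.08 and mean 0.03), MHC class II (0.634), complement (0.0905), ER stress (0.0678), glycolysis and hypoxia (0.906) and mitochondrially encoded mRNAs (0.753). Neither did the markers pass of monocytes (0.425), pluripotent cells (0.634), neural cells (0.575), endothelium (0.177), erythroid cells (0.459), mast cells (0.398) and epithelium (0.634). Of these, some passed with 1 library left out: ER stress (0.0079) and monocyte markers (0.0294) without WT replicate 1, complement (0.0114) without GRN KO replicate 1, and cholesterol synthesis without WT replicate 3 (0.00569) or WT replicate 4 (0.0439).

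Across all genes, 703 of 16776 passed in GRN KO against WT, 418 up and 285 down, and 278 of them by at least 2-fold. The count depended on single libraries, since it was 2226 without WT replicate 2, 299 without WT replicate 3, 283 without WT replicate 4, 224 without GRN KO replicate 2 and 229 without GRN KO replicate 3. The batches differed too, with 336 genes past the threshold for a genotype effect that differed between them. The log2 fold change, sign included, was higher in B for 294 and higher in A for 42, which does not say where the effect was stronger.

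The comparison of TMEM106B KO with WT asked what loss of TMEM106B alone changes, and rests on 2 libraries of batch B. The pooled fit uses 1 batch difference for all genotypes, which only WT, GRN KO and Double KO can inform. The effect against WT differed between the batches in 336 genes for GRN KO and 1126 for Double KO. For such genes the WT level set against TMEM106B KO is shifted, so pooled values can depart from those of batch B alone. CTSF, a lysosomal cysteine protease, had 0 counts in both TMEM106B KO libraries, and in batch B it was at least 15.1-fold lower than in WT, at 1.81 ± 0.134 CPM against a floor of 0.12 CPM set by 3 counts in 1 library. It also had 0 counts in all 4 Double KO libraries, and whether this is a property of the lines, of the counting or of the deletion was not tested. MHC class II genes were lower as a group, with 7 of 11 members down and 0 up (9 down adjusted over the list alone), and a median log2 of -0.49. The camera adjusted p was 4.71e-13, with adjusted p = 0.159 with an estimated correlation, and fry, which tests movement one way, gave an adjusted p of 0.0116. HLA-DRA fell 1.48-fold (log2 -0.57, SE 0.10, adjusted p = 0.00855), with 1874 and 1786 CPM against 2601 ± 71.5 in WT of batch B. The call ended without TMEM106B KO replicate 2 at nearly the same size (log2 -0.53, adjusted p = 0.143), and reads of HLA genes can be shared between near-identical copies. PURPL, a long noncoding RNA, fell 5.89-fold (log2 -2.56, SE 0.33, adjusted p = 0.00115). MRC1, the mannose receptor, fell 3.15-fold (log2 -1.65, SE 0.28, adjusted p = 0.00764; 0.0996 without TMEM106B KO replicate 2). TNF fell 1.91-fold (log2 -0.93, SE 0.16, adjusted p = 0.00574; 0.0744 without TMEM106B KO replicate 2). Its list had 0 members up and 2 down, with and a camera adjusted p of 0.0519, which passed without WT replicate 1 (0.0241), WT replicate 3 (0.0438), WT replicate 4 (0.0478) or TMEM106B KO replicate 1 (0.0435).

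Markers of other cell types were much higher in TMEM106B KO, beside all the changes above. Of 13 fibroblast or mesenchymal markers, 9 rose and 0 fell (11 rose adjusted over the list alone), with a median log2 of 6.88, a camera adjusted p of 6.46e-14 and adjusted p = 0.159 with an estimated correlation. Scores were 5.76 in replicate 1 and 7.75 in replicate 2. COL1A1, a collagen chain of connective tissue, reached 139 and 704.9 CPM against 0.139 ± 0.0233 in WT of batch B and 34.7 ± 15.3 in WT of batch A. COL1A1 rose by 7.59 on the log2 scale in the pooled test (SE 1.27, adjusted p = 0.0116; 0.118 without TMEM106B KO replicate 2 and 0.0549 without WT replicate 3). COL6A3, another collagen chain, rose 70.5-fold (log2 6.14, SE 0.70, adjusted p = 0.00176), to 20.01 and 101.2 CPM. PDGFRA, a growth factor receptor of mesenchymal cells, rose 15.1-fold (log2 3.92, SE 0.50, adjusted p = 0.00113). KDR, the endothelial VEGF receptor, rose 105-fold (log2 6.71, SE 0.96, adjusted p = 0.00348), to 2.08 and 16.0 CPM. The KDR call ended in batch B alone, at a larger difference (log2 7.66, adjusted p = 0.0653). With only the groups compared the calls of KDR (log2 7.66, adjusted p = 0.112), COL6A3 (log2 7.23, adjusted p = 0.0927) and COL1A1 (log2 11.51, adjusted p = 0.0677) ended, also at larger differences than in the pooled test. In all, 3 of 5 endothelial markers rose (3 adjusted over the list alone; camera adjusted p = 0.000107, adjusted p = 0.159 with an estimated correlation). Epithelial or hepatic markers kept their call in both tests (3 of 7 up, 7 adjusted over the list alone; camera adjusted p = 3.72e-07 and adjusted p = 0.0309 with an estimated correlation). Pluripotent stem cell markers had 2 of 5 up (3 adjusted over the list alone; camera adjusted p = 0.00058, 0.0743 without TMEM106B KO replicate 2, adjusted p = 0.243 with an estimated correlation), with scores of 0.77 and 2.47. PODXL, a surface sialomucin, rose 8.48-fold (log2 3.08, SE 0.59, adjusted p = 0.0133), a call lost without WT replicate 3 (0.0901), WT replicate 4 (0.0842) or TMEM106B KO replicate 2 (log2 1.66, adjusted p = 0.165). Extracellular matrix genes had 5 of 23 up (8 adjusted over the list alone; camera adjusted p = 4.04e-07, adjusted p = 0.321 with an estimated correlation), among them THBS1, which encodes thrombospondin 1 and rose 22.8-fold (log2 4.51, SE 0.69, adjusted p = 0.00295). Lysosomal proteins had 0 of 49 members up and 1, CTSF, down (camera adjusted p = 0.851, median 0.03 and mean -0.15, the mean set by CTSF). In batch B alone, which holds all TMEM106B KO libraries, 18 of 49 rose and 1 fell, with a median of 0.17 and a camera adjusted p of 2.21e-05. Also in batch B alone, monocyte markers had 4 of 10 up and 1 down (median 0.30, camera adjusted p = 0.00358). Cholesterol efflux and LXR targets had 5 of 14 up and 1 down there (camera adjusted p = 8.18e-05). In the pooled test by DESeq2, 1 monocyte marker and 1 LXR target rose and 0 fell in either list. In all, 629 genes passed, 501 up and 128 down, 465 of them by at least 2-fold. The count was 277 without WT replicate 3, 305 without WT replicate 4 and 201 without TMEM106B KO replicate 2, and the left-out fit with 1 TMEM106B KO library assumes that it varies like the other groups.

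The comparison of Double KO with WT asked what remains changed when both genes are absent. MNDA, a nuclear protein of myeloid cells, rose 18.7-fold (log2 4.23, SE 0.25, adjusted p = 4.4e-06), to 76.4 ± 4.84 CPM in batch A and 15.1 ± 0.965 in batch B against 3.57 ± 0.749 and 0.956 ± 0.0895 in WT. It was 20.2 and 19.8 CPM in TMEM106B KO and 3.64 ± 1.24 in GRN KO. ADGRE1, the human homologue of the mouse macrophage marker F4/80, rose 6.19-fold (log2 2.63, SE 0.37, adjusted p = 0.00336). ADCY1 rose 8.94-fold (log2 3.16, SE 0.39, adjusted p = 0.00174), close to its rise in GRN KO, with 63.3 ± 13.4 CPM (n = 4) against 64.9 ± 29.6 in GRN KO (n = 3). HSPA1A, an inducible heat-shock protein, fell 21.6-fold (log2 -4.43, SE 0.12, adjusted p = 1.58e-10); it shares reads with the near-identical HSPA1B and its level is uncertain. AKAP17A and ASMTL, which have copies on both sex chromosomes and are likewise uncertain, fell 7.39-fold (log2 -2.89, adjusted p = 2.04e-07) and 2.61-fold (log2 -1.39, adjusted p = 6.47e-06). CTSF was at least 105-fold lower than WT in batch A and at least 13-fold lower in batch B, with a floor of 3 counts per library. OLFML3, a gene of homeostatic microglia, fell 1.51-fold (log2 -0.60, SE 0.06, adjusted p = 0.000131). The homeostatic list went both ways, with 5 of 20 members higher and 7 lower at an unadjusted p under 0.05. In batch B alone 7 rose and 7 fell (camera adjusted p = 0.998).

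Extracellular matrix and adhesion genes were higher in Double KO, with 9 of 23 members up and 0 down (12 up adjusted over the list alone), a median log2 of 1.01 and a camera adjusted p of 1.69e-07, but adjusted p = 0.564 with an estimated correlation. Their medians were 0.42 in batch A (1 of 22 rose, camera adjusted p = 6.84e-06) and 1.49 in batch B (14 of 23 rose, camera adjusted p = 1.26e-20). MMP9, a gelatinase, rose 3.8-fold (log2 1.93, SE 0.32, adjusted p = 0.00765), and VCL, a focal adhesion protein, rose 2.26-fold (log2 1.18, SE 0.12, adjusted p = 0.000204). Mesenchymal markers had scores of -0.64 and 1.09 in the Double KO libraries of batch A and 2.78 and 3.63 in those of batch B. Of these 13 markers 0 passed in edgeR, 2 were higher at an unadjusted p under 0.05 and 1 by DESeq2. The camera adjusted p was 0.0273 (0.0599 without WT replicate 3 and 0.13 without Double KO replicate 2), with adjusted p = 0.564 with an estimated correlation. Lysosomal proteins had 13 of 49 members up and 1, CTSF, down (24 up and 2 down adjusted over the list alone; camera adjusted p = 2.08e-06, adjusted p = 0.564 with an estimated correlation). GLA, a lysosomal galactosidase, rose 1.51-fold (log2 0.59, SE 0.11, adjusted p = 0.00582). The lysosomal scores were -0.04 and -0.08 in batch A (camera adjusted p = 0.679 there) and 0.48 and 0.48 in batch B. NF-kB targets had 1 of 22 members up and 2 down (3 up and 2 down adjusted over the list alone; camera adjusted p = 0.598), with scores of 0.04, 0.09, 0.28 and 0.17. MHC class II genes had 0 of 11 up and 2 down (2 down adjusted over the list alone; median -0.13, camera adjusted p = 0.0371, adjusted p = 0.564 with an estimated correlation). Their call ended without WT replicate 1 (0.131), WT replicate 2 (0.112), Double KO replicate 1 (0.34) or Double KO replicate 2 (0.0624), and their scores were -0.40 and -0.22 in batch A and 0.09 and 0.06 in batch B. TNF still fell 1.70-fold (log2 -0.76, SE 0.12, adjusted p = 0.00317), and TRAF1, an adaptor of TNF receptors, rose 1.52-fold (log2 0.60, SE 0.11, adjusted p = 0.00531). Interferon genes had 0 of 38 past edgeR's threshold (1 lower at an unadjusted p under 0.05 and 0 by DESeq2; camera adjusted p = 0.617, but 0.00985 without WT replicate 4), with scores of -0.74 and -0.87 in batch A and 0.94 and 0.39 in batch B. Further lists passed camera's threshold, none with an estimated correlation. By DESeq2, 8 of 25 disease-associated microglia genes rose and 2 fell. In autophagy 4 of 25 rose, in cholesterol synthesis 5 of 24 and among mitochondrially encoded mRNAs 2 of 13, and 0 fell. Without WT replicate 1 the camera calls of these lists ended (adjusted p = 0.0503, 0.0543, 0.109 and 0.0994, in this order).

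Of all genes, 1833 passed in Double KO against WT, 1129 up and 704 down, 562 of them by at least 2-fold. The count was 3362 without WT replicate 2, 791 without WT replicate 3, 648 without WT replicate 4, 669 without Double KO replicate 3 and 673 without Double KO replicate 4. In 1126 genes the effect differed between the batches. The log2 fold change, sign included, was higher in B for 733 and higher in A for 393.

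Double KO against GRN KO is the comparison closest to the question in the title, that of TMEM106B loss in cells with a GRN knockout. These groups also differed in IRAK4, PUS7L and EHHADH, as given below, so differences between them cannot be credited to TMEM106B alone. NF-kB targets were higher in Double KO, with 9 of 22 members up and 0 down (19 up adjusted over the list alone), a median log2 of 0.80, a camera adjusted p of 7.3e-28 and adjusted p = 0.000526 with an estimated correlation. TNFAIP3 rose 2.08-fold (log2 1.06, SE 0.09, adjusted p = 2.7e-05), to 155 ± 17.0 CPM (n = 4) from 71.7 ± 6.86 (n = 3), beside 145 ± 31.0 in WT. CXCL8 rose 3.12-fold (log2 1.64, SE 0.17, adjusted p = 0.000211), and TNF rose by 1.03 on the log2 scale (adjusted p = 0.00155). The list's median was 0.58 in batch A, from 1 GRN KO library and with 0 of 22 members past edgeR's threshold (13 higher at an unadjusted p under 0.05), and 0.79 in batch B (18 members rose, camera adjusted p = 2.1e-36). Monocyte markers were higher beside them, with 5 of 10 higher and 1 lower at an unadjusted p under 0.05. Their camera call was lost without GRN KO replicate 1 (adjusted p = 0.0517) and with an estimated correlation. In batch B alone 4 rose and 1 fell (camera adjusted p = 0.00136). The same libraries differed in IRAK4, which was 9.18 log2 units higher in Double KO (SE 0.24, adjusted p = 2.28e-10), in PUS7L (log2 8.99, SE 0.27, adjusted p = 4.65e-10) and in EHHADH, 25.5-fold higher (log2 4.67, SE 0.18, adjusted p = 4.98e-09). FRY, a microtubule-associated protein, rose 19.1-fold (log2 4.25, SE 0.30, adjusted p = 6.33e-06). CSF2RA fell 10.6-fold (log2 -3.41, SE 0.21, adjusted p = 9.92e-06) and HSPA1A 11.6-fold (log2 -3.54, SE 0.13, adjusted p = 3.6e-09), both uncertain in their counting.

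Homeostatic microglia genes were lower in Double KO than in GRN KO, with 5 of 20 members down and 0 up (9 down adjusted over the list alone; median -0.22, camera adjusted p = 3.3e-06, adjusted p = 0.177 with an estimated correlation). BIN1, a membrane-bending protein and a risk gene of Alzheimer's disease, fell 2.16-fold (log2 -1.11, SE 0.14, adjusted p = 0.0012), from 187.7 ± 67.3 to 78.5 ± 13.8 CPM. GPR34, a lysophospholipid receptor, fell 1.32-fold (log2 -0.40, SE 0.06, adjusted p = 0.00192). Interferon genes had 0 of 38 up and 1 down (10 down adjusted over the list alone), a median of -0.80, a camera adjusted p of 6.36e-13 and adjusted p = 0.557 with an estimated correlation, with medians of -0.31 in batch A and -0.89 in batch B. Lysosomal proteins were not separated in the pooled test, with 1 of 49 up and CTSF down (2 up and 3 down adjusted over the list alone). Their median was -0.03, their mean, set by CTSF, was -0.17, and the camera adjusted p was 0.317 (0.00156 without GRN KO replicate 1). CTSF was at least 32.6-fold lower than in GRN KO in batch A and at least 11.6-fold lower in batch B, from the same floor. Mesenchymal markers had a median log2 of 5.90, with 0 of 13 past edgeR's threshold (8 up at an unadjusted p under 0.05 and 8 by DESeq2, 5 up adjusted over the list alone). Their camera adjusted p was 1.37e-06, with adjusted p = 0.557 with an estimated correlation. Beside them, extracellular matrix genes had 2 up and 1 down (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.00205, 0.378 without GRN KO replicate 1, adjusted p = 0.653 with an estimated correlation). Over all genes 451 passed, 297 up and 154 down, 204 by at least 2-fold. The count was 209 without GRN KO replicate 2, 223 without GRN KO replicate 3, 235 without Double KO replicate 3 and 273 without Double KO replicate 4. 28 genes had an effect that differed between the batches.

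Double KO against TMEM106B KO asked what loss of GRN changes in cells without TMEM106B, with the TMEM106B KO libraries in batch B only. Its pooled values carry the same limit of the shared batch term as TMEM106B KO against WT. GRN fell by 5.58 on the log2 scale (SE 0.28, adjusted p = 5.79e-06). Mesenchymal markers were lower in Double KO, with 8 of 13 down and 0 up (11 down adjusted over the list alone; camera adjusted p = 2.63e-08, adjusted p = 0.382 with an estimated correlation). Beside them, lysosomal proteins had 2 of 49 up and 0 down (9 up adjusted over the list alone; median 0.22, camera adjusted p = 9.9e-07, adjusted p = 0.632 with an estimated correlation), and 30 up and 0 down in batch B alone. MHC class II genes had 1 of 11 up and 0 down (8 up adjusted over the list alone; median 0.36, camera adjusted p = 7.59e-06, adjusted p = 0.382 with an estimated correlation), and 10 up and 0 down in batch B alone. NF-kB targets were not lower, with 2 of 22 up and 0 down (3 up and 2 down adjusted over the list alone; median 0.25, camera adjusted p = 0.0117, 0.0553 without TMEM106B KO replicate 2, adjusted p = 0.382 with an estimated correlation). TMEM106B itself was lower in Double KO (log2 -1.56, SE 0.38, adjusted p = 0.0405). A total of 774 genes passed, 312 up and 462 down, with 90 left without Double KO replicate 3, 117 without Double KO replicate 4 and 48 without TMEM106B KO replicate 2.

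The interaction asked whether both deletions together differ from the sum of their single effects. It includes TMEM106B KO and so carries the limit of the shared batch term. It also cannot tell an interaction of the deletions from a difference between lines, such as that in IRAK4. NF-kB targets had 8 of 22 members with a positive interaction and 0 with a negative one (12 and 0 adjusted over the list alone), a median log2 of 0.84, a camera adjusted p of 3.66e-23 and adjusted p = 0.00103 with an estimated correlation. TNF had an interaction of 1.96 (adjusted p = 0.000595), TNFAIP3 of 1.33 (adjusted p = 0.000586) and IRAK4 of 8.89 (adjusted p = 4.56e-09), all on the log2 scale. MHC class II genes had 0 of 11 past edgeR's threshold (8 positive at an unadjusted p under 0.05 and 5 by DESeq2, 8 positive adjusted over the list alone). Their median was 0.43 and the camera adjusted p 2.38e-05, with adjusted p = 0.777 with an estimated correlation. Lysosomal proteins had 0 of 49 past edgeR's threshold (3 positive and 2 negative at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.616). In total 258 genes had an interaction, 132 positive and 126 negative. That count was 481 without WT replicate 2, 128 without WT replicate 3, 146 without WT replicate 4, and 128 without GRN KO replicate 2. It was 136 without GRN KO replicate 3, 68 without TMEM106B KO replicate 2, 108 without Double KO replicate 3 and 119 without Double KO replicate 4.

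Of the 703 genes changed in GRN KO, 150 moved towards WT in Double KO and 7 moved further away. Since IRAK4 and PUS7L differed between GRN KO and Double KO too, these counts cannot be credited to TMEM106B loss alone. IRAK4, PUS7L, EHHADH, TNF, TNFAIP3 and CSF2RA were among those that moved back, while ADCY1, with a rise of 3.27 in GRN KO and 3.16 in Double KO on the log2 scale against WT, was not. Choosing genes on the GRN KO libraries favours movement back by chance, so the same was read from separate libraries. Over 3366 genes chosen in batch B, the GRN KO library of batch A had a signed median of 0.1344 on the log2 scale, with 72.7% of genes moved in the batch B direction. The Double KO libraries of batch A had 0.0994 and 0.0926, with 63.9 and 65.2%. Over the 100 genes with the lowest p, Double KO replicate 1 lay above the GRN KO library (0.7624 against 0.5656) and replicate 2 below it (0.3281). Batch A held 1 GRN KO library, so no test was made, and the GRN KO median was 0.0495 without WT replicate 1 and 0.2144 without WT replicate 2, beside Double KO means of 0.0219 and 0.1789. The count of 150 was 277 without WT replicate 2, 61 without GRN KO replicate 2, 67 without GRN KO replicate 3 and 94 without Double KO replicate 3. The count of 7 was 13 without WT replicate 1, 42 without WT replicate 2, 3 without WT replicate 3, and 1 without WT replicate 4. It was 4 without GRN KO replicate 1, 1 without GRN KO replicate 2 or 3, 18 without Double KO replicate 2, 4 without Double KO replicate 3 and 3 without Double KO replicate 4.

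**Figure D4:**
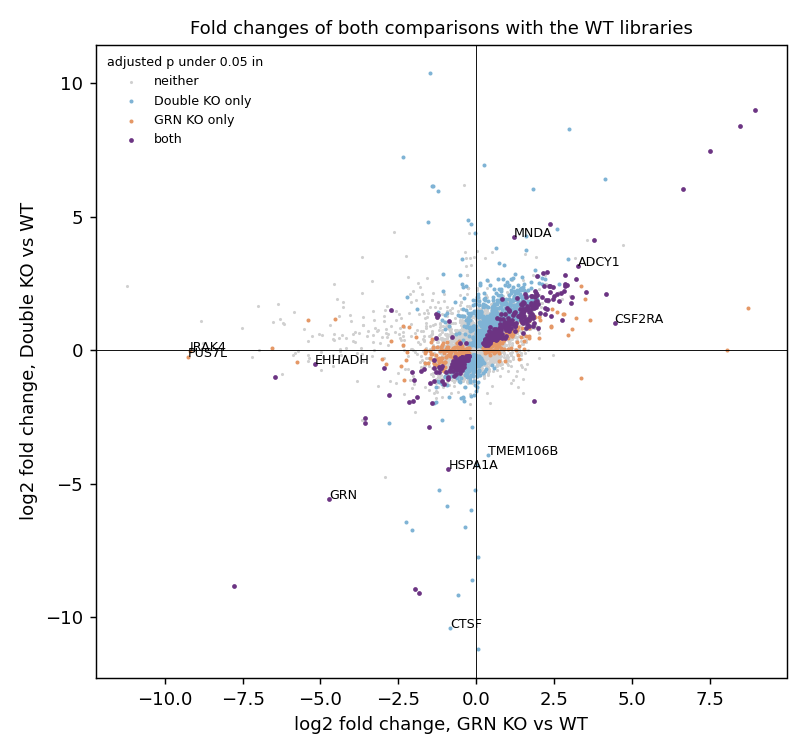
Log2 fold change of every tested gene in GRN KO against WT (horizontal axis) and in Double KO against WT (vertical axis), 1 point per gene, coloured by the comparison in which its adjusted p was under 0.05. IRAK4 and PUS7L lie at the far left near 0 on the vertical axis, and 255 genes rose and 109 fell in both.

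The profiles of GRN KO and Double KO against WT had a correlation across genes of 0.365 and a covariance of 0.1399, where genes are not independent replicates. Unchanged groups simulated against the same WT libraries gave a mean correlation of 0.456 (0.418 to 0.496) and a covariance of 0.035, so that the covariance differed by 0.1049. ADCY1, VCL and DPP4 were among 255 genes up in both, where independent lists would share 28.1, and 109 were down in both, where 12 would be shared, and 10 went opposite ways. With separate WT libraries the correlation was 0.239, and within batch B it was 0.617, or 0.425 with a separate WT library for each comparison. TMEM106B KO and Double KO had a correlation of 0.478 and a covariance of 0.2878 against 0.0354 simulated. They had 138 genes up in both (33.7 by independence), 59 down in both (5.4) and 4 opposite. CTSF was among those down, and MNDA among those up (log2 4.37 in TMEM106B KO, adjusted p = 3.69e-05). GRN KO and TMEM106B KO had a negative correlation of -0.138 and a covariance of -0.0861 against 0.0393 simulated, and the sign turned in batch B alone, which holds all TMEM106B KO libraries. There the correlation was 0.283 and the covariance 0.2371, and with separate WT libraries the correlation was 0.197. In the pooled test these groups had 65 genes up in both (12.5), 42 down (2.2) and 8 opposite.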

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

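Of the tests that weigh explanations, those with the second NF-kB list and the second mesenchymal list were fixed before their results were seen, and the others, the divisions of the libraries included, were chosen afterwards.

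The tested list of NF-kB targets was lower in GRN KO and not in Double KO, with scores below WT in the GRN KO libraries of both batches. If loss of GRN lowered these targets whatever the TMEM106B genotype, they would be lower in Double KO than in TMEM106B KO. Their median log2 difference there was 0.25, not the direction that this needs. The comparison was chosen after the pattern was known and largely restates it. The TMEM106B KO libraries also held markers of other cell types, so no conclusion is drawn from it. Loss of IRAK4 and PUS7L in the GRN KO libraries may be a property of that line, and lower IRAK4 may in turn lower NF-kB targets. A second list of 19 targets had a median of -0.151 (SE over genes 0.166) in batch A and -0.039 (SE over genes 0.265) in batch B, with 10 lower in both. In batch B its members went both ways, from EHD1 at -1.62 to CCRL2 at 1.53. The second list as a whole thus showed no decrease beyond its SE over genes in either batch, and the decrease is shown for the first list only. The batch B value lies on the side of -0.1 named beforehand as counting against IRAK4, by less than its SE over genes. That SE takes the genes as independent and holds no spread between libraries, and the condition on it was applied only after the value was seen. The value therefore does not decide, and the IRAK4 explanation stays open. TMEM106B deletion in GRN knockout cells, with an interaction at adjusted p = 0.00103 with an estimated correlation, cannot be told apart from it, because IRAK4 differs between the same libraries and no GRN KO library kept it.

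Markers of other cell types were higher in TMEM106B KO. A candidate explanation for the mesenchymal part is an admixture of mesenchymal cells, larger in replicate 2. It was set to need a median log2 ratio of at least 1 in a second mesenchymal list. All 18 of 18 members of that second list were higher in replicate 2 than in replicate 1, with a median log2 ratio of 1.27. Its most abundant members in replicate 2 were S100A6 at 83.5 and 90.7 CPM (62.9 in WT of batch B), SERPINH1 at 44.0 and 74.4 (38.3), FBLN1 at 12.2 and 72.8 (6.36) and COL6A1 at 42.0 and 62.7 (26.9), with 8 of the 18 at 1 CPM or more in WT of batch B. The first mesenchymal list was already known to be higher in replicate 2, and such genes vary together, so this outcome was likely beforehand. It compares 1 library with 1, and a deletion effect of unequal size in them would give it too, so it does not decide. Epithelial or hepatic markers (scores 2.72 and 3.19) and pluripotent stem cell markers (0.77 and 2.47) were higher too, which leaves open what other cells were present, and no sort or gate is given in the sources used here. TMEM106B loss itself was set to need a call of the mesenchymal list in Double KO against GRN KO with an estimated correlation, which was not reached. The lowest Double KO score also lay under the lowest WT library of its batch (a difference of -0.297), an outcome set as counting against it. That value came from 1 library and was less than the spread of WT scores in that batch, a condition applied after the value was seen. Both Double KO libraries of batch B lay above WT, so TMEM106B loss stays open. COL1A1 was also found in WT of batch A, as given above, and so without the deletion.

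Among the 35 ways to divide the WT and GRN KO libraries into groups of these sizes, 2 called at least the 703 genes of the real one, so chance cannot be excluded by this count. The highest other division called 2015 genes and moved WT replicate 2 to the GRN KO side, several times the real count, which points to a structure of the samples. A mislabelled WT replicate 2 is argued against by its GRN level, 39.2 times that of the highest GRN KO library. A difference in cell state between the WT libraries of batch A could account for it but stays open: over the genes that GRN KO changed in batch B, WT replicate 2 differed from WT replicate 1 by a signed median of 0.1725, below the 0.2144 of the GRN KO library from the same reference. That test rests on the libraries that raised the question.

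For Double KO against WT, 1 of 35 divisions, the real one with 1833 genes, was as large (highest other 576). For Double KO against GRN KO it was again 1 of 35, the real one with 451 genes (highest other 377, the division that follows the batches). Both shares are under 0.05, but only 18 of the 35 divisions keep the real number of libraries of each batch in each group. Among those 18 the real one was again the only one as large in both comparisons (highest other 576 for Double KO against WT and 39 for Double KO against GRN KO), and 18 are too few for a share under 0.05. For GRN KO against WT 2 of 18 were as large.

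Single libraries far from the other 3 of their group were found in 11 of 228 groups of 4 tested for 114 named genes, and chance alone gives about 1 in 20 where a group's libraries are of 1 kind. These groups held 2 libraries of each batch, and most genes differed by batch, so that rate does not hold as it stands. In CPM, these were DDIT4L in Double KO replicate 4 at 232 (others 215 to 217) and CTSB in Double KO replicate 1 at 4630 (others 4280 to 4340). PDGFRA in Double KO replicate 4 was at 0.36 (others 0.171 to 0.186). Double KO replicate 2 accounted for COL1A2 at 93.4 (others 6.04 to 20.1), COL1A1 at 102 (others 6.79 to 18.0), COL5A2 at 16.1 (others 0.558 to 3.07), HLA-DRB1 at 1120 (others 967 to 992) and CD55 at 27.0 (others 31.8 to 32.2). In WT, PURPL stood at 2.09 in replicate 2 (others 3.69 to 3.83), SPNS2 at 14.3 in replicate 1 (others 3.63 to 5.32) and ARSB at 103 in replicate 2 (others 86.5 to 88.0).

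By the interaction test, Double KO differed from the sum of the single effects in 20 of the named genes reported. IRAK4, PUS7L and EHHADH were nearly lost in the GRN KO libraries and not in Double KO. COL6A3 rose in TMEM106B KO beside markers of other cell types. Differences between lines therefore cannot be told apart from an interaction of the deletions. Most of these genes were also named for large changes in the same libraries. On the log2 scale the interaction was positive for IRAK4 at 8.89 (adjusted p = 4.56e-09), PUS7L at 8.66 (1.29e-08), EHHADH at 4.26 (4.53e-07), TMEM176B at 3.17 (1.03e-05) and MIR3142HG, a microRNA host gene, at 3.14 (0.000664). It was also positive for FPR1, a formyl peptide receptor, at 2.96 (adjusted p = 0.00299), PURPL at 2.87 (0.00278), MRC1 at 1.98 (0.0191) and CHMP4C at 1.96 (0.0137). Among NF-kB targets, with a list median of 0.84 (adjusted p = 0.00103 with an estimated correlation), it was 1.96 for TNF (adjusted p = 0.000595), 1.84 for CXCL8 (0.00401), 1.33 for TNFAIP3 (0.000586), 1.08 for TRAF1 (0.0126) and 0.85 for NFKBIA (0.00137). Negative interactions were -7.84 for CSF2RA (adjusted p = 8.01e-07), -5.44 for COL6A3 (0.0322), -3.43 for HSPA1A (2.5e-07), -1.90 for AKAP17A (0.000844), -1.29 for MMP2 (0.0302) and -1.27 for FAM149A (0.0254). CSF2RA, AKAP17A and HSPA1A share reads with near-identical copies, so their values are uncertain.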

How the results depend on the processing

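The fit with 1 mean per genotype and batch, the list counts by batch, the splits of WT within batch B and the added settings for the overlap of TMEM106B KO with Double KO or GRN KO were tests chosen after the results were seen. Of 1621 values of named genes under other settings, 1368 kept direction and side of the threshold, 246 lost the threshold, 7 gained it and 0 changed direction; 94 of the losses came without a batch term, 87 in batch A alone and 46 with only the groups compared. With 1 library left out, 817 of 1073 kept their call and 256 lost it. For lists, 508 of 672 values under other settings kept their call, 122 lost it, 32 gained it and 10 changed direction, and 737 of 816 kept it with 1 library left out. Scaling by RLE or upper quartiles and a non-robust spread kept every count within 1.5 times, and left the medians of all genes between -0.0223 and 0.0125. Depth of 21521850 to 27750488 counts limits what can be said of genes near the floor of 3 counts, and the small groups, with 2 TMEM106B KO libraries and 1 GRN KO library in batch A, limit every test. No paired analysis was possible because replicate numbers were given in accession order only and pair no libraries. For all changes named here the cause was not tested, except that fewer libraries or genes enter where the setting says so.

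Counts of genes are given in the order GRN KO, TMEM106B KO and Double KO against WT, Double KO against GRN KO, Double KO against TMEM106B KO, interaction, genes towards WT and genes away, where the setting moved them by over 1.5 times. Without a low-count filter they were 2320, 1747, 3108, 1538, 2706, 1197, 612 and 158. Without a batch term they were 59, 283, 193, 88, 149, 35, 22 and 0. In batch B alone they were 4336, 2288, 5436, 2007, 4574, 1807, 746 and 509. With the DESeq2 Wald test GRN KO against WT gave 1307, Double KO against GRN KO 800, Double KO against TMEM106B KO 1319, the interaction 523, towards WT 264 and away 20. With CPM of at least 1 in at least 4 libraries, TMEM106B KO against WT gave 328 and Double KO against TMEM106B KO 439. With a size threshold of 2-fold the counts were 278 for GRN KO against WT, 562 for Double KO against WT, 204 for Double KO against GRN KO, 436 for Double KO against TMEM106B KO, 61 towards and 4 away. In batch A alone GRN KO against WT gave 19, Double KO against WT 66, Double KO against GRN KO 28, towards WT 6 and away 0. With only the groups compared, Double KO against WT gave 705, against GRN KO 1013 and against TMEM106B KO 3385. With 1 mean per genotype and batch the counts were 1673, 1197, 3269, 827 and 2919 for the comparisons of genotypes, 280 towards and 52 away.

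Leaving out 1 library gave 224 to 2226 genes for GRN KO against WT, 201 to 930 for TMEM106B KO against WT, 648 to 3362 for Double KO against WT, 209 to 515 for Double KO against GRN KO, 48 to 1144 for Double KO against TMEM106B KO, 68 to 481 for the interaction, 61 to 277 towards WT and 1 to 42 away. Lists past the threshold numbered 8 to 11, 6 to 10, 7 to 13, 6 to 11 and 11 to 12 in the order of the comparisons of genotypes. The held-out signed median was 0.0495 to 0.2144 for GRN KO and 0.0219 to 0.1789 for Double KO. A lone TMEM106B KO library was assumed to vary like the other groups.

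Lists past camera's threshold numbered 10, 7, 13, 8 and 12. Without a batch term they were 6 for GRN KO, 12 for TMEM106B KO and 8 for Double KO against WT, and in batch B alone 13 for TMEM106B KO. With an estimated correlation 1, 1, 0, 1 and 0 were left, and with fry 1, 4, 2, 3 and 1. Direction changed without a batch term for cholesterol synthesis in Double KO against TMEM106B KO (adjusted p = 0.00341). In batch B alone it changed for TMEM106B KO against WT in lysosomal proteins (2.21e-05), interferon response (0.0148) and cell cycle (0.00193), for Double KO against WT in interferon response (0.0106) and MHC class II (0.822), and for Double KO against GRN KO in cell cycle (0.000879). In batch A alone, with 1 GRN KO library assumed to vary like the other groups, it changed for GRN KO against WT in cholesterol efflux and LXR targets (0.000187), interferon response (0.000155) and extracellular matrix and adhesion (0.00117).

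The correlation across genes of GRN KO and Double KO was 0.239 with separate WT libraries, 0.617 in batch B and 0.425 in batch B with separate WT libraries. That of TMEM106B KO and Double KO was 0.408 with separate WT libraries, 0.414 without a batch term, 0.675 in batch B and 0.526 in batch B with separate WT libraries. Unchanged groups were not simulated within batch B. Held-out signed medians of GRN KO and Double KO were 0.5656 and 0.5453 for the 100 genes with the lowest p and 0.3487 and 0.2955 for 500 genes, where Double KO replicate 1 lay above GRN KO (0.7624 and 0.366) and replicate 2 below (0.3281 and 0.225). They were 0.1202 and 0.0862 for genes with a mean log2 CPM of at least 1.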

Other observations

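The counts of list members that passed within each batch were tests chosen after the results were seen. Cell cycle genes were lower in Double KO than in WT, with 0 of 28 members up and 2 down (9 down adjusted over the list alone). The median log2 was -0.47 and the camera adjusted p 2.08e-06, with adjusted p = 0.564 with an estimated correlation. The same list was lower in Double KO than in TMEM106B KO (median -0.47, 1 down, 6 down adjusted over the list alone, camera adjusted p = 1.05e-06, adjusted p = 0.622 with an estimated correlation), while mesenchymal markers differed between these groups too. In batch B alone all 28 members fell in GRN KO and in Double KO against WT, with medians of -0.66 and -0.81, and in batch A the medians were -0.52, from 1 GRN KO library, and -0.09. In batch A 0 of 28 members passed edgeR's threshold in either comparison, and 0 had an unadjusted p under 0.05. V-ATPase subunits, which acidify the lysosome, had 3 of 18 up and 0 down in Double KO against WT (5 up adjusted over the list alone, camera adjusted p = 0.00237, adjusted p = 0.564 with an estimated correlation). In batch B alone 13 of 18 rose (camera adjusted p = 2.31e-06), and in batch A 0 of 18 passed edgeR's threshold, with 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.582). ATP6V0A2 rose 1.31-fold (log2 0.39, SE 0.05, adjusted p = 0.00089) and ATP6V1B2 rose 1.37-fold (log2 0.46, SE 0.08, adjusted p = 0.00422).

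ER stress genes had 1 of 21 members up and 6 down in Double KO against WT (2 up and 8 down adjusted over the list alone). The camera adjusted p was 0.0148 (0.158 without WT replicate 2), with adjusted p = 0.564 with an estimated correlation. The ER stress medians were -0.12 in batch A and -0.14 in batch B (camera adjusted p = 0.0486 and 0.116). XBP1, a transcription factor of the unfolded protein response, fell 1.26-fold (log2 -0.33, SE 0.06, adjusted p = 0.00749). SLC2A3, a glucose transporter, rose 1.47-fold (log2 0.55, SE 0.08, adjusted p = 0.00194), in a glycolysis and hypoxia list with 6 of 24 up and 0 down (6 up adjusted over the list alone). That list's camera adjusted p of 0.0396 was lost without WT replicate 1 (0.103), WT replicate 2 (0.093), WT replicate 3 (0.0614), Double KO replicate 1 (0.27) or Double KO replicate 2 (0.0624), and it had adjusted p = 0.564 with an estimated correlation. Its medians were 0.15 in batch A and 0.07 in batch B (camera adjusted p = 0.00288 and 0.822). In complement, CD55, which restrains complement on the cell surface, rose 1.86-fold (log2 0.89, SE 0.13, adjusted p = 0.00107). C1QC, a chain of the first component, fell 1.37-fold (log2 -0.45, SE 0.08, adjusted p = 0.00521). That list had 4 of 18 members up and 3 down (5 up and 3 down adjusted over the list alone, camera adjusted p = 0.0993; 0.0482 without WT replicate 2). SCD, a fatty acid desaturase, rose 1.45-fold (log2 0.54, SE 0.09, adjusted p = 0.00424). Endothelial markers had 3 of 5 up in Double KO against WT (3 adjusted over the list alone, camera adjusted p = 0.00526, adjusted p = 0.564 with an estimated correlation), beside the matrix and mesenchymal genes above. VWF, a clotting factor carrier of endothelium, had a log2 difference of 1.91 (adjusted p = 0.0149; 0.0534 without WT replicate 3). S100A12, a calgranulin of monocytes, fell 7.53-fold in GRN KO against WT (log2 -2.91, SE 0.46, adjusted p = 0.00361). CDH1, which encodes E-cadherin, rose 2.74-fold in GRN KO (log2 1.46, SE 0.20, adjusted p = 0.00278) and 2.10-fold in Double KO (log2 1.07, SE 0.19, adjusted p = 0.00695).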
